A study of Mus musculus with 2 samples.

How the data were processed

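Islets of 2 mice per strain were isolated by collagenase digestion (0.45 mg/ml, 16 min), a Ficoll gradient and picking by hand, in buffer with 16.7 mM glucose, per the labels' protocols, and pooled before RNA was extracted. Each strain was one group of 1 library, so the design has 2 groups with no replicates.

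The deposited file of each library lists 94545 Ensembl mouse transcripts of 38924 genes without a header. Its first value per transcript is the expected count that the authors obtained with RSEM, which divides reads that match several transcripts among them, on the genome build GRCm38, per the submitters' processing notes. The second value was read as the fraction of all transcript molecules that the authors' RSEM run assigned to the transcript. One reason is that it sums to 1 in each deposited file. The other is that the count divided by it followed transcript length among well-counted transcripts. That rank correlation was 0.962 across 9697 transcripts in B6 and 0.965 across 10747 in CAST. Rescaled by the usual factor, the second value is TPM. The aligner, versions, read length and layout, library kit, strand setting and annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Both libraries were quantified on the reference build, so reads from CAST carry strain variants against it.

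Expected counts were summed per gene and rounded to whole numbers. Of 38924 gene IDs 37607 were matched to a symbol, position and transcript type in GENCODE M21 (GRCm38), and the unmatched IDs held 0.176% of counts in B6 and 0.172% in CAST. Library totals were 76600903 and 104324631 counts. TMM factors from edgeR 4.0.16 were 1.056 for B6 and 0.947 for CAST (R 4.3.3). The log2 ratio is that of CAST over B6 of scaled counts with 0.5 added to each, for genes with 100 or more counts over both libraries. Its 95% interval is the exact Clopper-Pearson interval of the CAST share of a gene's counts, turned into a ratio; it and the floor of 3 counts per library cover counting error only, since reads are not independent molecules. A gene with 0 counts in a library has a ratio only as a bound against that floor. A gene was detected at a TPM of 1 or more.

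There were 27 gene lists, chosen from general knowledge of islets, of the cell types that isolated islets can carry and of protein modification. List members needed 20 counts over both libraries, and a list 4 members for a median, which left out the strain label checks. Each median was placed among medians of 10000 random lists of the same size drawn from 40 bins of mean expression. The genes named in the text follow this rule: the 12 per direction whose counting interval lies farthest from equality, leaving out predicted genes, pseudogenes and small RNAs by symbol; the 2 highest and 2 lowest members of each list with 100 or more counts; the 10 genes of highest TPM per library; all hormones and strain checks; and the 6 genes with the largest loss of share of the B6 main transcript. Partners and copies of these genes, Hspa8 and Rpl3 in the plot of copies, the sex-linked genes, the acinar genes outside the list and the genes opening the other observations were chosen after their values were seen. Some genes that the rule names are not reported here.

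Near-identical copies were found by aligning the longest GENCODE transcript of each gene to all others with minimap2 2.31. A pair counted with 95% identity, gaps counted once, over at least 200 bases and 50% of the shorter transcript; 5991 of 37607 genes had one. Values of genes with a copy are uncertain, because RSEM divides shared reads.

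The computation of ratios was tested on simulated data, with counts drawn from the mean of both libraries at the real library sizes. Of 50 genes simulated at 2.5-fold and 50 at 5-fold higher in CAST, 100% came out at least 2-fold, as did 97.8% of 45 genes at 0.4 and 100% of 44 at 0.2; of 14571 unchanged genes 0% did, and the interval covered the true ratio for 95.3% of them. Of 200 unchanged random lists 4.5% lay outside the central 95%. These 200 lists were drawn at random from the same genes as their comparison lists, so they check the computation only. How often lists of co-expressed genes would lie outside was not simulated. The simulations hold no variation between mice.

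The groups, ratios, thresholds, lists, naming rule and most alternatives (other scalings with DESeq2 1.42.0 size factors, total counts or TPM with a pseudocount of 1, other count filters, thinning, transcripts taken separately) were fixed before the data were examined. The alternatives that sum or leave out near-identical copies were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The protein part of the study was not analysed here.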

Results

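RNA was sequenced from pancreatic islets, the endocrine cell clusters of the pancreas, of C57BL/6J (B6) mice, the laboratory strain on which the mouse reference genome is based, and of CAST/EiJ (CAST) mice, an inbred strain derived from wild Mus musculus castaneus. The labels describe the mice as male and 10 weeks old. Islets of 2 mice per strain were pooled, 250 islets of each pool went to RNA, and the remaining 400 B6 and 470 CAST islets went to protein analysis. There was 1 library per strain, with 76600903 expected counts for B6 and 104324631 for CAST. No replicate error can be estimated from 1 library per strain, so no difference between the strains was tested. Ratios compare these 2 libraries, and the 95% intervals given with them cover counting error only. The series concerns a protein database search for modified peptides, and the RNA gives the list of genes and transcripts present in the same islets.

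Ins2, an insulin gene, was the most abundant gene in both libraries. It (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381, GRCm38) made up 40.4% of transcripts in B6 and 47.8% in CAST, and Ins1, the second mouse insulin gene, which in B6 came after the glucagon gene Gcg, 5.44% and 5.54%. On the scale of TMM-scaled counts Ins2 was 1.51-fold and Ins1 1.30-fold higher in CAST. Gcg was 1.29-fold higher in B6 (log2 ratio of CAST over B6 -0.36, 95% interval -0.37 to -0.36), and Sst, which encodes somatostatin, 1.86-fold higher in B6 (log2 -0.90, -0.91 to -0.89). Ppy, the pancreatic polypeptide gene, was 1.56-fold higher in CAST, and Ghrl, the ghrelin gene, had 482 counts in B6 and 1990 in CAST (log2 1.76, 1.61 to 1.90). Iapp, the islet amyloid gene, and Pyy differed by log2 -0.01 and 0.04. When the deposited fractions were compared as TPM they differed by -0.36 and -0.32, where the median of all genes was itself -0.26. The 8 hormone genes together held 24.9% of counts in B6 (exact Clopper-Pearson interval 24.90 to 24.92) and 28.4% in CAST (28.38 to 28.40).

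Genes of alpha cells, the glucagon cells, lay lower in CAST as a group. Of 10 members 8 had a ratio below 0, and their median log2 ratio of -0.49 was at percentile 0.10 of 10000 random lists of the same size and mean expression, as a description of these libraries. Irx1 and Irx2, transcription factors of alpha cells, were 1.93-fold and 1.84-fold higher in B6, whereas Pou3f4, with 28 and 96 counts, differed by log2 1.47. The list of delta and PP cells had a median of -0.36 (percentile 1.54), with 5 of 7 members below 0 and the peptide genes Ppy (0.64) and Pyy (0.04) above. Its lowest member was Ghsr, the ghrelin receptor gene, with 455 counts in B6 and 215 in CAST (log2 -1.37, -1.61 to -1.13). Genes of beta cell identity and glucose sensing had a median of 0.01 (percentile 37.6), and each of the 23 was within 2-fold. Their extremes were Trpm5 (log2 0.74) and Slc2a2, the glucose transporter gene (0.63), at the upper end, and Isl1 (-0.63) and Neurod1 (-0.53), transcription factors, at the lower end. The CAST library, in which these endocrine genes were set against B6, also had the higher share of acinar transcripts, given next.

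Digestive enzyme genes of acinar cells, the exocrine cells around the islets, were higher in CAST. Of the 27 genes of the acinar list 25 were at least 2-fold higher in CAST, none was at least 2-fold higher in B6, and the median log2 ratio was 2.04 (4.11-fold, percentile 100). The list held 0.888% of counts in B6 (exact interval 0.886 to 0.890) and 3.61% in CAST (3.61 to 3.62). Ctrb1, which encodes a chymotrypsin precursor (chromosome 8, 111686519 to 111691010), had 92908 counts in B6 and 412177 in CAST (log2 1.86, 1.85 to 1.87). Amy2b, an amylase gene annotated as a pseudogene, had 368 and 703091 counts, and Prss1, a trypsinogen gene, 47 and 16269; both have near-identical copies, and with the copies added the log2 ratios were 1.94 and 1.34. The acinar transcription factor genes were the lowest members: Bhlha15 differed by log2 0.17 (0.11 to 0.22), and Ptf1a, with 55 and 91 counts, by 0.43 (-0.06 to 0.95).

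Markers of stellate cells and fibroblasts were also higher in CAST, with a median log2 ratio of 0.91 over 12 genes (percentile 100) and 5 genes at least 2-fold higher. Thy1, a surface protein gene, was 6.83-fold higher and Lum, a matrix proteoglycan gene, 3.30-fold higher, while Rgs5 and Pdgfrb, pericyte genes, differed by log2 -0.04 and 0.04. Duct genes had a median of 0.33 (percentile 97.51, counting interval -0.09 to 0.58) with members in both directions, and their share of counts went the other way, 0.0365% in B6 and 0.0267% in CAST. Krt19, a keratin gene, had 54 counts in B6 and 764 in CAST, and Muc1 169 and 526, whereas Ambp was 2.14-fold higher in B6. Endothelial genes had a median of 0.23 (percentile 97.6), with Vwf at log2 1.44, Plvap at 0.49, Egfl7 at -0.23 and Emcn at -0.29. Leukocyte genes had a median of 0.23 (percentile 92.3), with Csf1r at 0.71, Itgam at 0.60, Cd79a at -0.71 and Adgre1 at -0.77. Genes of Schwann cells and adipocytes had 6 measured members and a median of 0.40 (percentile 89.3), with S100b at 1.67, Gfap at 0.82 and Fabp4 at -1.14. By TPM the duct, endothelial, leukocyte and Schwann cell medians were below 0 (-0.0012, -0.06, -0.08 and -0.08), where the median of all genes was itself -0.26.

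**Figure D1:**
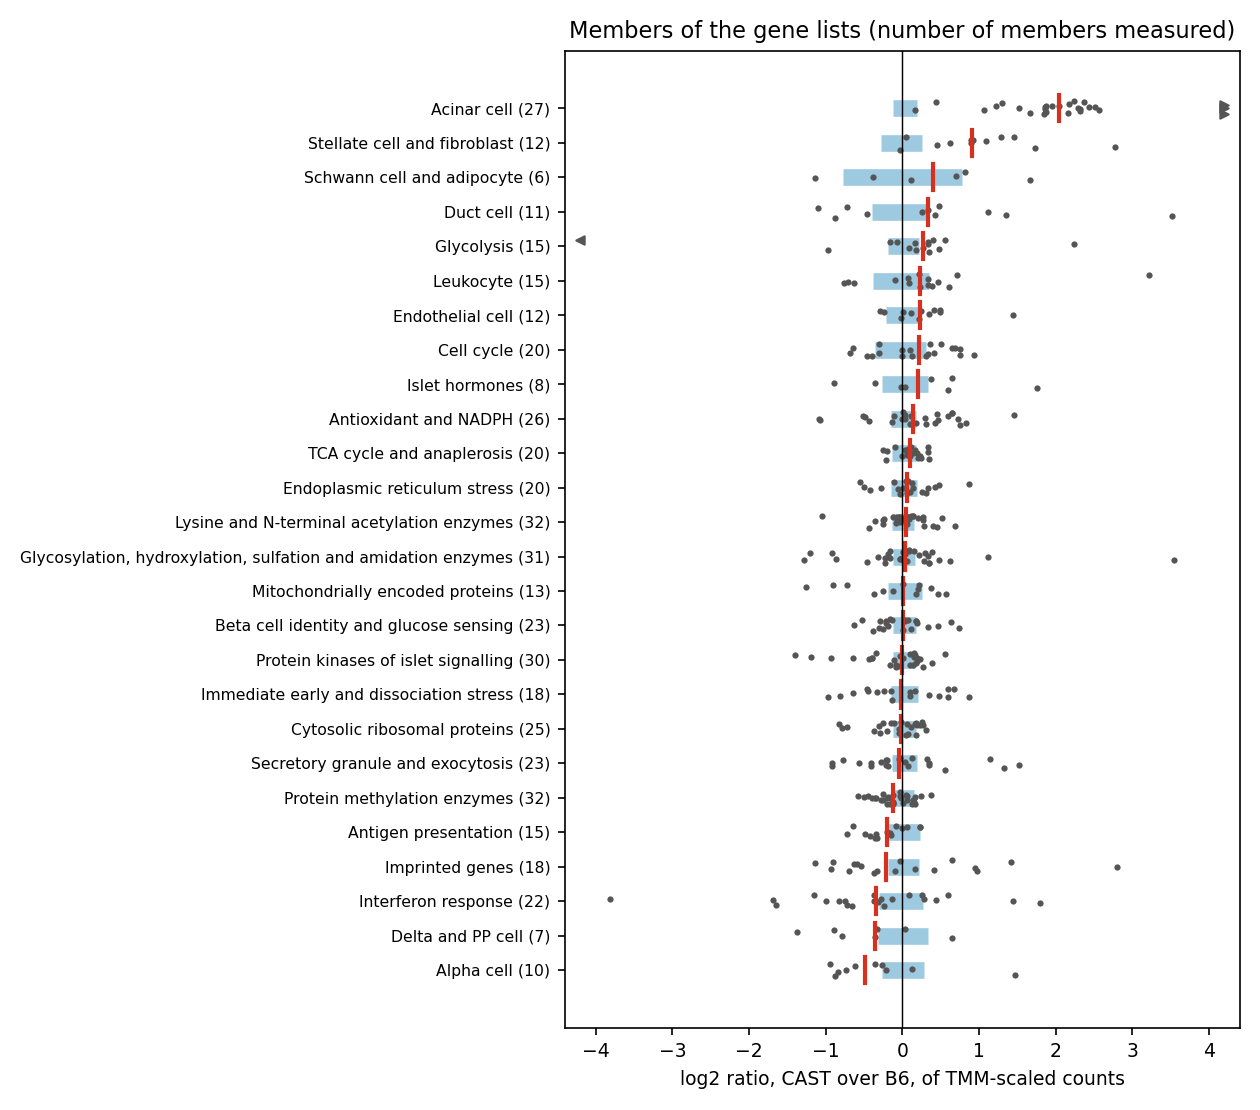
Log2 ratio of CAST over B6 of TMM-scaled counts (horizontal axis) for the measured members of 26 gene lists (vertical axis), 1 library per strain. Points are genes, red lines list medians, blue bars the central 95% of medians of 10000 random matched lists, and triangles 4 members beyond 4.2; the acinar median lies at 2.04 and the alpha cell median at -0.49.

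Across all genes the libraries were close in detection and differed by 2-fold or more in a minority. At a TPM of 1 or more 12811 genes were detected in B6 and 12540 in CAST, of which 11994 were shared. Of 14768 genes with 100 or more counts over both libraries, 12823 (86.8%) were within 2-fold. There were 1060 genes at least 2-fold higher in CAST and 885 at least 2-fold higher in B6, and at 4-fold 506 and 198. With near-identical copies summed, 811 and 804 genes were at least 2-fold and 295 and 173 at least 4-fold higher in CAST and in B6, and among genes with no copy 758 and 766 at least 2-fold. The split also differed between scalings: 54.5% of the 2-fold genes were higher in CAST with TMM factors, and 44.1% with total-count scaling (926 and 1173 genes). By TPM it was 38.6% (463 and 737), where the constant added before the ratio is also another, so that scaling is not set apart. Of transcripts counted separately with TMM factors, 2611 and 3585 were 2-fold apart, 42.1% of them higher in CAST. The median log2 ratio of all genes was 0.02 with TMM, -0.14 with total counts and -0.26 by TPM, and directions of single genes are to be read relative to it.

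**Figure D2:**
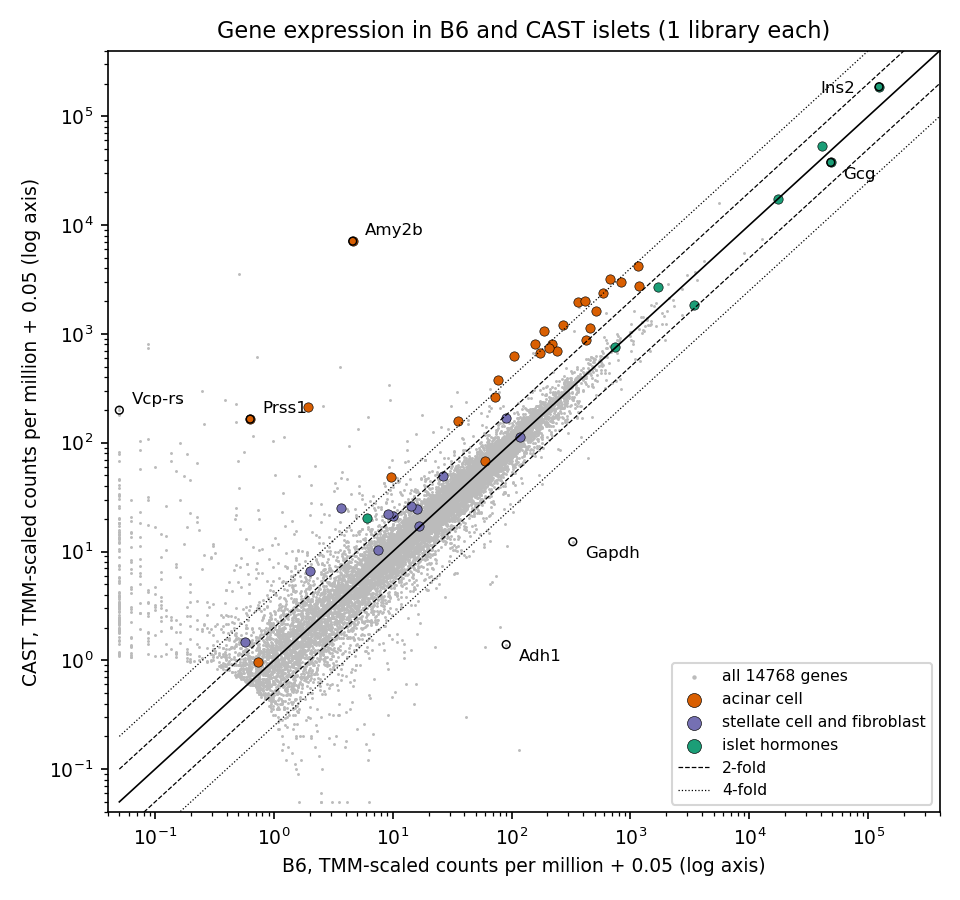
TMM-scaled CPM (counts scaled to library size) in B6 (horizontal) and CAST (vertical), with 0.05 added, both on log axes, for 14768 genes with 1 library per strain; dashed and dotted lines mark 2-fold and 4-fold. Acinar genes lie above the diagonal, with Ctrb1 at 3.63-fold, while Gapdh and Adh1 lie far below it, 26.7-fold and 66.5-fold higher in B6; with its copies added Gapdh differed by log2 0.23.

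The genes with the largest ratios included several whose sequence is nearly the same as that of another gene. Vcp-rs, a processed copy of the ATPase gene Vcp (chromosome X, 104345829 to 104348234), had 0 counts in B6 and 19662 in CAST, at least 5364-fold higher against a floor of 3 counts per library; with Vcp added, the log2 ratio was 0.11. Rps3a2, a ribosomal protein copy, had 16 and 29787 counts, BC002163, a copy of Ndufs5, 0 and 2452 (at least 669-fold), and Eno1b, a copy of the enolase gene Eno1, 3 and 3105 (log2 9.50, 8.18 to 12.00); with their copies added the log2 ratios were 0.01, 0.00 and 0.02. Hmga1b, at 3 and 1719 counts, came to 0.19 with Hmga1 added, and the histone gene Hist1h2al, at 0 and 1180, to -0.37. C87414 had 0 and 1439 counts and its copies 0 and 55. Gapdh, which encodes a glycolytic enzyme, went the other way, with 26437 counts in B6 and 1210 in CAST (log2 -4.74, -4.82 to -4.66), while its 49 copies had 5111 and 44038, and the sum differed by log2 0.23.

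**Figure D3:**
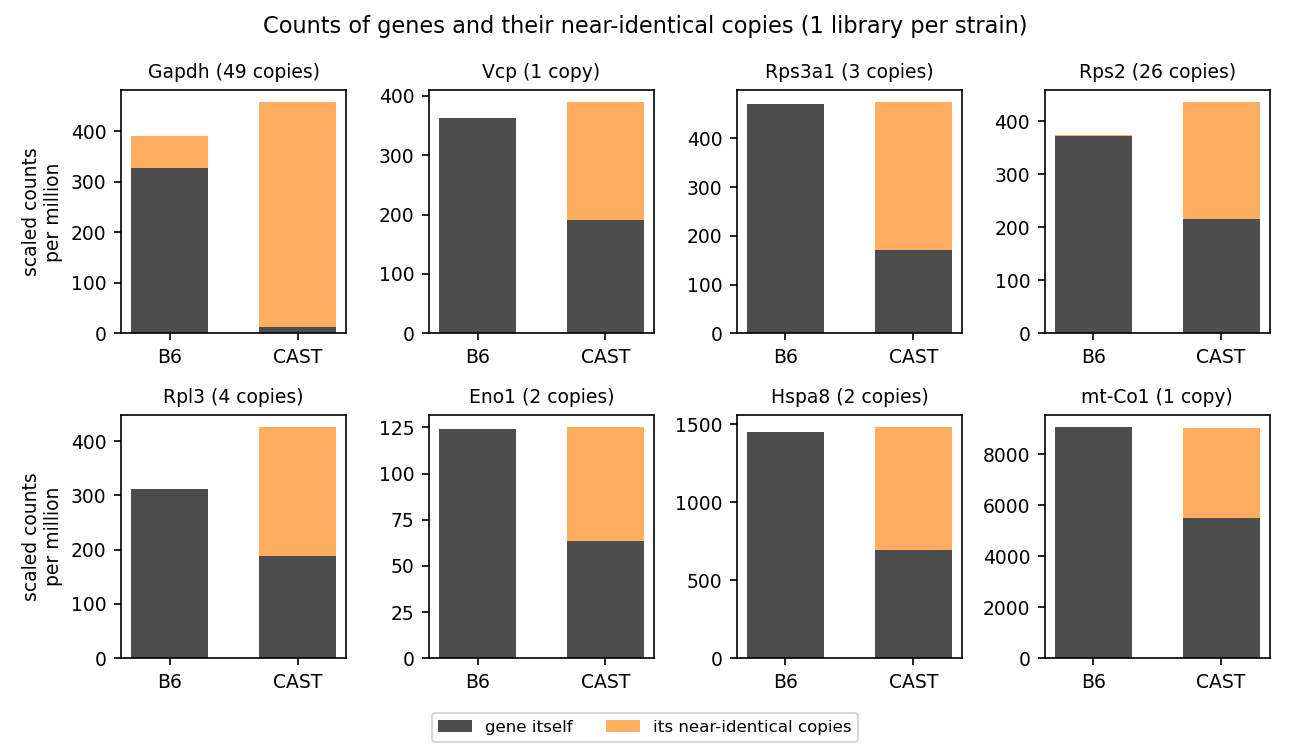
TMM-scaled CPM (vertical axes from 0) of 8 genes and of all their near-identical copies stacked on them, in B6 and CAST, 1 library per strain. The copies hold a larger part of the counts in CAST than in B6: Hspa8 differed by log2 -1.06 alone and by 0.03 with its copies, and mt-Co1 by -0.72 and -0.01.

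Genes with no such copy found also stood far apart. The search counted near-identical transcripts only, so reads shared with less similar genes were not tested for these ratios. Cela3a, an elastase gene, had 3 counts in B6 and 10666 in CAST (log2 11.28, 9.96 to 13.78), AK157302 0 and 3821 (at least 1042-fold) and Gsdma3, a gasdermin gene, 0 and 743. The ratio of Cela3a lay far above that of the acinar list, whose median was 4.11-fold higher in CAST, and its cause was not tested. Higher in B6 were Naip2, a sensor gene of the inflammasome, with 3358 and 25 counts (log2 -7.33, -7.99 to -6.79), and Adh1, an alcohol dehydrogenase gene (chromosome 3, 138260991 to 138290698), with 7270 and 133 (-6.06, -6.32 to -5.81). Kcnip1, a potassium channel partner, had 4816 and 126 counts, Zfp783 1219 and 34, Cdh7, a cadherin gene, 1274 and 55, Ugt1a6a, a glucuronosyltransferase gene, 1039 and 55, and Dct 476 and 12. The noncoding gene Rptoros had 245 and 0 counts. Plppr1 (738 and 26 counts), Hist1h4m (197 and 0) and Tgtp2 (508 and 10) have copies, and with these added the log2 ratios were -5.04, -1.67 and -0.48.

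Genes of the interferon response lay lower in CAST, with a median log2 ratio of -0.34 over 22 genes (percentile 1.45), 4 at least 2-fold higher in B6 and 2 at least 2-fold higher in CAST. Ifi44 had 351 counts in B6 and 30 in CAST (log2 -3.82, -4.43 to -3.30), and Ifih1, a sensor of viral RNA, 1775 and 671. In the other direction were Mx2 (log2 1.79, 1.54 to 2.07) and Usp18, a negative regulator of interferon signalling (1.45, 1.36 to 1.53). Antigen presentation genes had a median of -0.20 (percentile 2.15), each of the 15 within 2-fold, with H2-K1 at -0.73, H2-D1 at -0.64, Cd74 at 0.22 and Psmb10 at 0.23. The B6 main transcript of H2-K1 held 77.3% of the gene's TPM in B6 and 34.8% in CAST. Reads of CAST were quantified on the B6 reference, and how far strain variants lower these ratios was not tested. Endoplasmic reticulum stress genes had a median of 0.06 (percentile 59.4), from Trib3 (-0.56) and Asns (-0.50) to Creld2 (0.48) and Sdf2l1 (0.87). Immediate early genes, which respond to tissue dissociation, had a median of -0.02 (percentile 28.8), from Btg2 (-0.98) and Zfp36 (-0.81) to Hspa1a (0.67) and Ier3 (0.87). Cell cycle genes had a median of 0.22 (percentile 92.3), and -0.08 by TPM, from Aurka (-0.69) and Ccna2 (-0.64) to Mcm3 (0.76) and Mcm5 (0.93). Their share of counts was lower in CAST, 0.0990% in B6 and 0.0846% in CAST.

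Secretory granule genes had a median near 0 (-0.05, percentile 12.9) with abundant members in both directions. Scg2, a granin gene (chromosome 1, 79434669 to 79440120), was 2.88-fold higher in CAST, with 450672 and 1584972 counts, and Scg5, which encodes a chaperone of the prohormone convertase PC2, 2.52-fold higher. Chga, another granin gene, was 1.71-fold higher in B6, Pam, the peptide amidating enzyme gene, 1.89-fold and Syt13 1.88-fold. Glycolysis genes had a median of 0.27 (percentile 99.3), and -0.07 by TPM, while their share of counts was lower in CAST (0.224% and 0.204%). That share leaves out near-identical copies. Those of Gapdh alone held 5111 counts in B6 and 44038 in CAST, so the direction of the share depends on whether they are counted. Slc16a1, a lactate transporter gene, had 67 and 387 counts, and Ldha was at log2 0.55. Gapdh and Eno1 were the lowest members of the list, at -4.74 and -0.97 alone, and at 0.23 and 0.02 with their copies added. TCA cycle genes had a median of 0.10 (percentile 84.8), and -0.24 by TPM and -0.05 with total counts, each of the 20 within 2-fold, from Idh3b (-0.25) and Me1 (-0.21) to Pdhb and Sdhb (0.34 each). Antioxidant genes had a median of 0.14 (percentile 93.8), and -0.18 by TPM and -0.01 with total counts, while their share of counts was lower in CAST (0.340% and 0.226%). Nqo1, a quinone reductase gene, was 2.73-fold higher in CAST, and Txnip, an inhibitor of thioredoxin, and Gpx3, a glutathione peroxidase gene, were 2.12-fold and 2.10-fold higher in B6. Mitochondrially encoded genes had a median of 0.01 (percentile 38.5), with mt-Nd3 at -1.26, mt-Co2 at -0.90 (-0.36 with its nuclear copy added), mt-Co3 at 0.17, mt-Atp6 at 0.46 and mt-Atp8 at 0.57. Cytosolic ribosomal protein genes had a median of -0.02 (percentile 26.3), with Rps2 at -0.79 (0.22 with its 26 copies added) and Rpl19 at 0.27.

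Enzymes that modify proteins differed little as groups. Lysine and N-terminal acetylation enzymes had a median of 0.04 (percentile 65.3), and 31 of 32 were within 2-fold. Sirt4, a mitochondrial sirtuin gene, was 2.08-fold higher in B6, and the others ranged from Hdac9 (-0.44) to Sirt5 (0.52) and Hdac11 (0.68). Protein methylation enzymes had a median of -0.12 (percentile 1.78), each of 32 within 2-fold, with Ezh1 at -0.57, Ezh2 at -0.50, Setd3 at 0.24 and Pcmt1 at 0.37. Enzymes of glycosylation, hydroxylation, sulfation and amidation had a median of 0.04 (percentile 52.2). Among them Qpct, which forms N-terminal pyroglutamate, had 269 counts in B6 and 3823 in CAST (log2 3.54, 3.36 to 3.72), Plod2, a lysyl hydroxylase gene, was 2.16-fold higher in CAST, and Man2a1, a Golgi mannosidase gene, and Tpst1, a tyrosine sulfotransferase gene, were 2.43-fold and 2.31-fold higher in B6. Kinases of islet signalling had a median of -0.01 (percentile 31.3). The insulin receptor gene Insr was 2.64-fold and Prkaa2, an AMPK catalytic subunit gene, 2.29-fold higher in B6, with Akt1 at 0.55 and Csnk2a2 at 0.39.

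Imprinted genes, expressed from the allele of a given parent, ranged widely, with a median of -0.22 over 18 genes (percentile 1.38). Nnat, which encodes neuronatin, was 6.99-fold and Peg10 2.66-fold higher in CAST, whereas Meg3, a noncoding RNA gene (chromosome 12, 109541001 to 109571726), was 2.21-fold and Plagl1 1.91-fold higher in B6. By TPM this list's median was at percentile 7.12, and without Meg3, its only member with a copy, at 14.3, both inside the central 95% of random lists. The copy of Meg3 had only 2 counts in each library, and Meg3 differed by log2 -1.14 with or without it. The move to 14.3 therefore reflects the loss of a low member and not shared reads.

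Most genes kept the same main transcript. Among 8981 genes with several annotated transcripts and 100 or more counts in each library, 8253 (91.9%) had the same most abundant transcript in B6 and CAST. In 133 genes (1.48%) another transcript was the most abundant in CAST and the B6 main transcript lost 30 or more percentage points of the gene's TPM, and in 85 of these both transcripts were annotated as protein coding. Nr5a2, a nuclear receptor gene with 111 and 179 counts, went from Nr5a2-202 with 7 exons (100% of its TPM in B6) to Nr5a2-201 with 9 exons (100% in CAST). Cep131, a centrosomal protein gene with 1643 and 2248 counts, went from Cep131-201 (87.8% in B6, 0.729% in CAST) to Cep131-202 (89.9% in CAST), whose lengths of 3578 and 3581 bases are close. Ccdc73 went from a noncoding transcript of 318 bases, Ccdc73-203, to the coding Ccdc73-201, Sema3b from Sema3b-204 to Sema3b-202, and Zfp708 from Zfp708-202 to Zfp708-201. Tgif2 lost a transcript with 93.9% of its TPM in B6 that has no entry in GENCODE M21. RSEM's uncertainty in dividing reads between transcripts is not given in the sources used here. CAST reads carry strain variants against the reference, and how far these move reads between transcripts was not tested. Hspa8, whose copies took up a large part of its counts in CAST, is among the 133 genes. Its B6 main transcript held 82.6% of its TPM in B6 and 7.44% in CAST.

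Strain and sex labels were checked on genes known to differ. H2-Ea-ps, a class II gene whose promoter is deleted in C57BL/6 mice, had 0 counts in B6 and 1786 in CAST, at least 487-fold higher, as the strain labels say. Nnt, part of which is deleted in C57BL/6J, had 2097 and 4571 counts (log2 0.83, 0.76 to 0.91), but its annotation on the B6 reference leaves out the deleted exons, so it checks nothing. Pla2g2a had 0 counts in each library. Xist, the RNA of the inactive X chromosome, had 96197 counts in B6 and 109595 in CAST. The Y-linked genes Eif2s3y, Kdm5d and Uty had 0 counts in both libraries and Ddx3y 1 and 0, which goes against the male sex in the labels of both. Uba1y, another Y-linked gene, had 66 and 50 counts; a count of 0 allows up to 0.0371 scaled CPM in B6 and 0.0304 in CAST.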

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

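The alternatives with near-identical copies were chosen after seeing the data. The number of genes detected stayed within 1.5 times of the main number in each library under a TPM of 0.5 or 5, a count of 10, and thinning to the shallower library. DESeq2 size factors, total counts, 5 added to each count and a counting interval past the fold kept all 4 numbers of genes past 2-fold and 4-fold within 1.5 times. The following settings moved numbers further. By TPM, 463 genes were at least 2-fold and 226 at least 4-fold higher in CAST, and 75 at least 4-fold higher in B6. With 20 counts, 1407 were 2-fold higher in B6, 788 4-fold higher in CAST and 355 4-fold higher in B6. With 500 counts the numbers were 592 and 455 at 2-fold and 278 and 83 at 4-fold (CAST and B6), with 1 count 3643 and 3240, and 1726 and 1017, and for separate transcripts 2611 and 3585, and 1095 and 921. At 4-fold higher in CAST, 245 genes were left without predicted genes, pseudogenes and small RNAs, 295 with copies summed and 270 among genes with no copy. Protein-coding genes with no copy gave 671 and 562 at 2-fold and 217 and 107 at 4-fold. Count filters and left-out genes alter how many genes enter; for TPM the cause was not tested beyond its median of -0.26 over all genes. Genes with another main transcript numbered 222 with 30 counts, 54 with 500, 728 with a loss of any size and 43 with a loss of 50 points. Of 26 list medians 14 changed sign by TPM, 7 with total counts and 3 without members that have copies. Among the 11 outside the central 95% of random lists, those turned by TPM were duct (-0.0012), endothelial (-0.062) and glycolysis genes (-0.073), all above the median of all genes, and 10 of the 11 stayed outside. Of 59 named genes that differed 2-fold, 59 did so in the same direction with DESeq2 size factors, 57 with total counts and 45 by TPM, and none reversed past 2-fold; of all 138 named, 16 within 2-fold changed sign by TPM and 3 with total counts. Depth limits genes under about 100 counts, and the single library per strain limits every ratio.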

Other observations

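Abundant genes outside the lists also differed between the libraries; the protein-coding genes named here are among the most abundant at least 4-fold apart with no copy found, and they and 2 noncoding RNAs were chosen after their values were seen. Npy, which encodes neuropeptide Y, had 744 counts in B6 and 33351 in CAST (log2 5.20, 5.09 to 5.30), and Th, the tyrosine hydroxylase gene of catecholamine synthesis, 5304 and 30691 (2.24, 2.20 to 2.29). Also higher in CAST were Ckb, brain creatine kinase (8.38-fold), Sncb, beta-synuclein (5.46-fold), Hspb8, a small heat shock protein (7.71-fold), Fam84a (28.1-fold) and Angptl7 (26.4-fold). Reg2 (26.2-fold), Gp2 (5.81-fold) and Amy1 (85.6-fold), genes with known exocrine expression, were higher in CAST beside the acinar list. Higher in B6 were Spc25, a kinetochore gene (log2 -2.11, -2.16 to -2.06), Lmo7 (-2.30), Pdyn, the prodynorphin gene (-2.13), Slc40a1, the iron exporter ferroportin (-2.33), Msln, mesothelin (-3.64), Defb1 (-3.69) and C8b (-3.71). The noncoding RNAs Neat1 and Malat1 had 35340 and 7148 counts (-2.59) and 61412 and 36361 (-1.05). Xist, named above among the sex-linked genes, differed by only -0.10. Lars2, a protein-coding gene, went the other way and was 4.50-fold higher in CAST. Across 12914 genes with no copy the log2 ratio had a rank correlation of -0.11 with transcript length and 0.01 with GC content.

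All tests in the paragraphs below were chosen after the result was seen, and no biological explanation other than strain is given by the design. Of 704 genes at least 4-fold apart, 269 (38.2%) had a near-identical copy, against 11.5% of the genes with a ratio, and 236 of the 269 were higher in CAST. If reads had moved from the most abundant copy, those partners should be lower in CAST. The 167 partners picked by their counts in B6, a choice that itself favours lower ratios, had a median log2 ratio of -0.10. This was below all of 10000 random matched lists (central 95% from -0.03 to 0.09). The 170 partners picked by their mean over both libraries, a choice that does not rest on B6 alone, had -0.09 (percentile 0.01). With the copies added the median of the 167 was 0.13. It was 0.29 for the 59 partners whose copies gained 25% or more of the partner's level in B6. Both were above equality, but these copies were chosen for being higher in CAST. CAST variants that bring reads nearer to a copy than to its parent are a candidate cause, and transcription of copies in CAST stays open. The 435 genes with no copy found, 270 higher in CAST and 165 in B6, are left unexplained.

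The acinar list stood 4.11-fold higher in CAST. The values argue against reads divided among near-identical copies, since the 22 members with no copy had a median of 2.10. They argue against a lower share of islet cells as the whole cause only if leukocytes lie outside the islets, which was not measured. The upper quartile of leukocyte genes (0.42) lay below the lower quartile of acinar genes (1.76). A smaller part played by a lower islet share cannot be told from this. The stellate cell (0.91), duct (0.33) and endothelial (0.23) medians were also above 0, while hormone genes held a higher share of counts in CAST. More acinar tissue in the CAST preparation may account for the higher acinar list. In that direction, 9 acinar genes outside the list that encode no secreted enzyme had a median of 1.88 (quartiles 0.61 and 2.04). They were picked after the list was seen to be higher, and include Cckar at 3.51, Pdia2 at 2.02 and Erp27 at 1.88. The transcription factor genes Rbpjl (0.36), Bhlha15 (0.17) and Ptf1a (0.43) were closer to equal, Gatm (-0.73) was higher in B6, and how many of these genes islet cells also transcribe is not given in the sources used here. Both preparations were purified by gradient and by hand, and how much acinar tissue was left in either is not known. A strain difference in acinar gene expression stays open and was not tested.

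Both libraries had abundant Xist, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at the floor. Xist ranked 46 among genes in B6 and 60 in CAST, and these 4 Y-linked genes summed to 1 count over both libraries. Male islets mixed with female RNA would bring reads of these 4, but the library with more of them had 1. The tables also argue against no Y chromosome among the transcripts quantified, since 173 of its genes are listed and, leaving out Gm47283 (10996 and 11061 counts) as taken to be shared with X, 4 had 10 or more reads: Uba1y (66 in B6 and 50 in CAST) and, with near-identical copies elsewhere, Mid1-ps1 (70 and 77, beside Gm47283), Gm20775 (21 and 1160) and Gapdh-ps15 (0 and 7840). Islets from female mice are a candidate explanation for both libraries, against the labels, and what the Uba1y reads come from was not tested.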
